A study of Homo sapiens with 3 samples.

How the data were processed

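Gene expression was measured by RNA sequencing in 3 libraries of DU145 cells, 1 each for the control P-Enter, wild-type BRAF (WT) and the mutant L597R. Per the labels' protocols, total RNA was taken with Trizol and made into libraries with a stranded mRNA kit. Per the submitters' processing notes, the tools were Trimmomatic, HISAT2, Cufflinks and HTSeq on hg38/GRCh38; versions, the strand setting of the counting and the annotation release were not given in the sources used here. Without that setting, reads of a gene and of an antisense partner cannot be assigned with certainty, and the same holds for near-identical copies and for overlapping genes.

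The authors deposited FPKM per Ensembl gene, per the file headers: reads scaled to the gene's length in kilobases and to the library's counted reads, with no further scaling stated. The design had been written before the data were examined for counts, with a fallback for FPKM. FPKM was found, so the fallback was used: a log2(FPKM + 1) difference of at least 1 and a mean over the 3 libraries of at least 1 FPKM, without an interval. No count model was fitted. All 23379 genes were above 0 in at least 1 library. Gene names came from a gene name table (23330 IDs matched), and positions, types, exon lengths and GC content from GENCODE 29 on GRCh38 (22807 IDs matched).

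FPKM computed from whole reads is a whole number of reads times a constant over the gene's length. Library totals and gene lengths were searched for that gave whole reads in all 3 libraries, within a tolerance of 1e-05. The totals were 13294004 (P-Enter), 15665132 (WT) and 16603676 (L597R), so 1 read was worth 0.0752, 0.0638 and 0.0602 CPM. Reads were recovered for 22594 genes (96.6%), of which 49.1% had exactly the exon length of the annotation and 88.1% lay within 10% of it. The recovered reads summed to 100.4% of each total (100.38 in P-Enter), and why they exceed it was not tested. On simulated data, 99.9% of 2829 genes came back exactly. Recovered reads gave the exact Clopper-Pearson 95% intervals of read ratios, conditional on the sum of both counts, and alternatives to the size rule. These were added after the values were seen. Polymerase chain reaction copies are not independent molecules, so intervals cover counting error only.

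The comparisons were WT with P-Enter, L597R with P-Enter and L597R with WT. Gene lists, 32 with 535 entries in all, were fixed before the data were examined. A list's median difference over members with a mean FPKM of at least 1 was ranked among 10000 random lists of the same size, matched in 20 bins of mean expression; this describes the libraries and is no test of the conditions. After the GC trend had been seen, the ranking was repeated on residuals of a regression with cubic terms in log length, GC content and log mean FPKM, fitted to 9358 protein-coding genes. Lists with fewer than 3 measured members were not ranked.

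Genes were named by a rule written beforehand: BRAF; members of the MAPK output list past the size rule; the 8 highest and 8 lowest genes past the rule with a symbol and a mean FPKM of at least 5; and up to 4 members past the rule from each list. Genes in opposite directions against P-Enter were named up to a number of 8. The protein-coding genes past the rule at a lower FPKM, and the list members given as examples without passing it, were chosen after their values were seen.

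The size rule was tested on simulated data with known changes and counting error only. Of 100 genes changed 3-fold it found 90% for WT against P-Enter, 91% for L597R against P-Enter and 83% for L597R against WT. Of 100 genes changed 1.6-fold it found 0%, 2% and 0%. Among 10639 genes tested it called 42, 40 and 32 unchanged genes, of which 3, 7 and 1 were 200 bp or longer. The simulated data held no variation between cultures and no GC trend, so these numbers do not give the rate of such calls in the real libraries. Overlap between the comparisons that share P-Enter was set beside 100 simulations of unchanged libraries.

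Alternatives were other pseudocounts (0.1 and 5), filters (none, and a mean of 5), thresholds (1.5 and 4), rescaling by the median ratio (factors 1.01, 0.998 and 0.998), leaving out mitochondrially encoded genes, protein-coding genes only, genes of 200 bp or longer, recovered reads and the regression. Reads from mitochondrially encoded genes were 2.01% in P-Enter, 2.01% in WT and 1.79% in L597R. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.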

Results

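RNA was sequenced from cells that the labels give as DU145, an established human line grown from a metastasis of a prostate carcinoma. The identity of the line rests on the labels, and the epithelial cadherin CDH1 had 1 read in P-Enter and 0 in the other libraries. There were 3 libraries, 1 in each of 3 groups: a negative control (P-Enter), cells overexpressing wild-type BRAF (WT) and cells transfected with a plasmid for the BRAF mutant L597R. BRAF is the serine/threonine kinase that passes signals from RAS to MEK and ERK, and the mutant has a single amino acid exchanged in the kinase domain. The values were FPKM for 23379 genes in each library. They rested on 13294004 counted reads in P-Enter, 15665132 in WT and 16603676 in L597R, worked out from the values themselves. With 1 library per group no difference below has a replicate check, and none has a p-value. Intervals are exact 95% intervals of a read ratio and cover counting error only, so they compare libraries and not conditions. A gene passed the size rule when its log2(FPKM + 1) differed by at least 1 between libraries and its mean FPKM was at least 1, which left 10639 genes to compare, 9358 of them protein-coding. Fold changes on this scale understate the change of low genes.

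BRAF was higher in WT and in L597R than in P-Enter, and higher in L597R than in WT. BRAF (ENSG00000157764) lies on chromosome 7 from 140719327 to 140924928 on the minus strand of GRCh38. Its level was 1.65 FPKM in P-Enter, 4.41 in WT and 9.59 in L597R, from 514, 1617 and 3733 reads. In CPM of all counted reads that was 38.7 (95% interval 35.4 to 42.2) in P-Enter, 103 (98.3 to 108) in WT and 225 (218 to 232) in L597R. The read ratio was 2.67 (2.42 to 2.95) for WT against P-Enter, 5.81 (5.30 to 6.39) for L597R against P-Enter and 2.18 (2.05 to 2.31) for L597R against WT. The labels give more BRAF in both libraries than in the control and no order between WT and L597R. FPKM values per gene do not separate plasmid from endogenous BRAF transcripts, or mutant from wild-type ones.

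**Figure D1:**
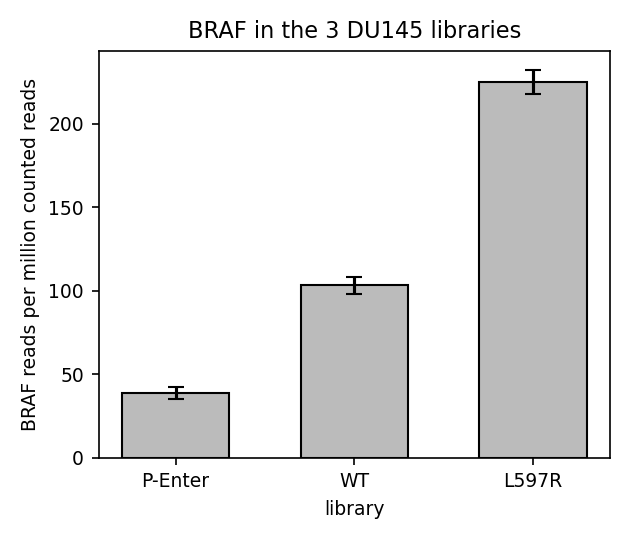
BRAF level in CPM, the reads scaled to library totals (y axis), in each of the 3 libraries (x axis); bars are the single value per library and error bars are exact 95% intervals for counting error only. The level was 38.7 in P-Enter, 103 in WT and 225 in L597R.

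The comparison of WT with P-Enter asked what went with more wild-type BRAF. Few protein-coding genes besides BRAF passed the size rule, 1 higher and 9 lower in WT; with recovered reads and an interval beyond 1.5-fold there were 10 higher and 36 lower. CDK7, the kinase of the CDK-activating complex and of TFIIH, was lower in WT at 1.96 FPKM against 8.03 (read ratio 0.243, 0.185 to 0.316). TMEM14C, a mitochondrial membrane protein needed for haem synthesis, was lower at 13.4 against 28.9 FPKM (0.463, 0.398 to 0.537). CDK7 lies on chromosome 5 from 69234795 to 69277430, and TMEM14C on chromosome 6 from 10722915 to 10731129. Values per gene do not tell a lower level of a transcript such as CDK7 from reads of its locus that were not aligned or counted.

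In all, 104 genes passed the rule, 40 higher and 64 lower in WT, but 76 of them were shorter than 200 bp. The 104 genes had a median of 6 reads over both libraries, and for 36 of them the interval of the read ratio left out 1. Among protein-coding genes 11 passed, 2 higher and 9 lower. Besides BRAF the higher one was SMDT1, a subunit of the mitochondrial calcium uniporter, at 3.02 against 0.999 FPKM. The other lower ones were ATP5IF1, MED18, NDUFS3, SURF1, MOAP1, NDUFA6 and UBL7. NDUFS3 and NDUFA6 belong to respiratory complex I. SURF1 and its neighbour SURF4 were both lower (log2 read ratios -1.80 and -1.32). Small nucleolar RNAs named by the rule rested on few reads. The libraries were made with an mRNA kit, and values per gene do not tell a short RNA from part of a longer transcript at the same place. This holds for the short RNAs of all comparisons. SNORD93 had 8 reads in WT and 1 in P-Enter (ratio 6.79, 0.910 to 301), and SNORD6 had 3 and 9 (0.283, 0.0493 to 1.13). SNORA11F had 14 and 31 (0.383, 0.188 to 0.742), and SNORD62B had 5 and 11 (0.386, 0.105 to 1.20).

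The list of transcripts used to read MAPK pathway activity had no higher median in WT. Of the 8 measured members none passed the rule, 7 lay below P-Enter and 1 above, and the list median was -0.09 on the log2 scale. SPRY4, a feedback inhibitor of receptor signalling, was at 19.7 against 22.7 FPKM (read ratio 0.868, 0.815 to 0.924). ETV5, an ETS transcription factor downstream of ERK, was at 9.72 against 10.9 FPKM, and DUSP6, the ERK phosphatase, at 6.07 against 5.48. DUSP4, a further phosphatase of the list below the filter of 1 FPKM, had 46 reads in WT and 21 in P-Enter (1.86, 1.09 to 3.28). That median lay at percentile 2.06 of 10000 random lists matched on expression, at percentile 9.24 without the filter and at percentile 8.86 after a regression on gene length, GC content and expression. The immediate-early and AP-1 genes had a median of -0.06 (percentile 2.92, and 8.47 after the regression). That list lay below the middle 95% with a pseudocount of 0.1 (percentile 0.570), with rescaling by the median ratio (2.06) and with recovered reads (0.300), while its median was 0.00 at a mean of at least 5 FPKM and 0.01 without a filter. The differences followed GC content across 9358 protein-coding genes (Spearman -0.45; genes are not independent replicates), so lists are given with the percentile before and after the regression.

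Of 27 ranked lists, 4 had a median above and 2 a median below the middle 95% of random lists. For lists of randomly drawn genes 1.35 would lie outside it. Members of a fixed list can vary together, so this number is no chance expectation for them. Of the lists put through the regression 2 lay outside after it, the metallothionein and oxidative stress genes and the TGF-beta and YAP targets. The latter had a median of 0.04 (percentile 95.7, and 98.4 after the regression). The metallothionein and oxidative stress genes had a median of 0.08 (percentile 99.8, and 100 after the regression), with GCLM, a subunit of the glutathione-synthesising ligase, at 27.8 against 23.3 FPKM. In that list 6 members lay above and 2 below P-Enter, and the metallothionein MT1E was lower at 378 against 431 FPKM (read ratio 0.878, 0.847 to 0.909). The heat shock genes had a median of 0.08 (99.7, then 96.0) and the mitotic genes 0.04 (99.7, then 96.5). The mitochondrially encoded mRNAs had a median of 0.05 (99.9, then 51.8). The long non-coding RNAs, at -0.10 (percentile 1.76), could not be put through the regression, which was fitted on protein-coding genes.

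The comparison of L597R with P-Enter asked the same of the mutant. MMP3, a secreted protease that degrades extracellular matrix, was higher in L597R at 4.13 against 0.933 FPKM (read ratio 4.42, 2.82 to 7.23; 127 reads against 23). RPS25, a protein of the small ribosomal subunit, was lower at 1.39 against 6.21 FPKM (0.223, 0.148 to 0.329). EIF3K, a subunit of translation initiation factor eIF3, was lower at 2.80 against 8.12 (0.345, 0.278 to 0.425), and EEF1B2, a subunit of an elongation factor complex, at 18.1 against 40.3 (0.450, 0.406 to 0.499). RPS25 was low in P-Enter as well, where the 30 listed ribosomal protein genes had a median of 277 FPKM and a lowest value of 9.19. Genes next to RPS25 and EIF3K, SLC37A4 and ACTN4, were lower in L597R too (log2 read ratios -1.80 and -1.25). MMP3 lies on chromosome 11 from 102835801 to 102843803, and RPS25 on chromosome 11 from 119015712 to 119018691.

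There were 86 genes past the rule, 32 higher and 54 lower in L597R, of which 62 were shorter than 200 bp. The interval left out 1 for 34 of the 86, and the median number of reads over both libraries was 7. Protein-coding genes made up 11 of them. With recovered reads and an interval beyond 1.5-fold, 12 protein-coding genes other than BRAF were higher and 40 lower. Besides BRAF, MMP3 was the other higher one by the size rule. Besides RPS25, EIF3K and EEF1B2 the lower ones were PSME2, NDUFS3, SURF1, H3C1, TRAPPC6A and SAMD1. Of these H3C1 had 3 reads in L597R and 14 in P-Enter, and TRAPPC6A had 4 and 20. Among genes of short RNAs, SNORD93 had 15 reads in L597R and 1 in P-Enter (ratio 12.01, 1.85 to 506), and SNORD83A had 5 and 19 (0.211, 0.0615 to 0.583). MIR4653 had 3 and 11 (0.218, 0.0391 to 0.827), MIR6739 had 2 and 7 (0.229, 0.0232 to 1.20), SNORD104 had 2 and 6 (0.267, 0.0263 to 1.49) and SNORD62B had 5 and 11 (0.364, 0.0991 to 1.14).

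The MAPK output list had no higher median in L597R either. All 8 measured members lay below P-Enter in the deposited values, none past the rule (DUSP6 by -0.01, less than the rescaling by the median ratio moves it), with a median of -0.12 (percentile 8.46, and 17.1 after the regression). CCND1, which encodes cyclin D1, was at 170 against 185 FPKM (read ratio 0.917, 0.895 to 0.941), and SPRY2 at 16.4 against 19.5 (0.841, 0.764 to 0.926). DUSP4, below the filter, had 47 reads against 21 (1.79, 1.05 to 3.16). The immediate-early and AP-1 genes had a median of -0.11 (percentile 5.87, then 73.7 after the regression). In that list FOSL1 was at 238 against 266 FPKM and EGR1 at 3.53 against 2.54. The cytosolic ribosomal protein genes had a median of -0.11, with 27 of 30 below P-Enter, at percentile 6.01 and then 0.440 after the regression.

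Lists of cytokine and stress genes had higher medians in L597R, with no member past the rule and with members in both directions. The NF-kB target and inflammatory cytokine genes had a median of 0.21 (percentile 98.7, and 99.7 after the regression); 8 of 11 measured members lay above P-Enter, and the interval lay above 1 for 5 of them and below 1 for 2. The list fell inside the middle 95% at a mean of at least 5 FPKM (median 0.11, percentile 83.8, 5 members) and without a filter (0.06, 94.9). Intervals leaving out 1 were also common in lists with medians inside the middle 95%. They lay above 1 for 4 and below 1 for 3 of 11 receptor tyrosine kinases and EGFR ligands (percentile 70.7). For 22 RAS-RAF-MEK-ERK components (percentile 66.7) they lay above 1 for 9 and below 1 for 7. CXCL8, the chemokine interleukin-8, was at 2.80 against 1.44 FPKM (read ratio 1.94, 1.35 to 2.83). CXCL2 was at 3.32 against 1.72 (1.93, 1.26 to 3.01) and BIRC3, an inhibitor of apoptosis, at 7.63 against 5.01 (1.52, 1.37 to 1.70). The metallothionein and oxidative stress genes had a median of 0.23 (percentile 99.9, then 100), with the interval above 1 for 6 of 8 and below 1 for 1. HMOX1, which degrades haem, was at 277 against 193 FPKM (1.44, 1.40 to 1.49), GCLM at 40.9 against 23.3 (1.76, 1.66 to 1.86) and TXNRD1, a thioredoxin reductase, at 284 against 207 (1.37, 1.35 to 1.40). The integrated stress response and unfolded protein response genes had a median of 0.11 (98.5, then 100), with 9 members above and 8 below P-Enter. Among them were SLC7A11, the cystine transporter, at 39.0 against 22.3 FPKM (1.75, 1.67 to 1.83), and HSPA5 at 188 against 206. The heat shock genes had a median of 0.21 (99.9, then 99.1), with 5 above and 4 below, but 0.09 at percentile 96.9 at a mean of at least 5 FPKM. The medians were 0.13 for the TGF-beta and YAP targets (98.9, then 98.0) and 0.06 for the mitotic genes (98.1, then 86.1).

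Lists of epithelial and mitochondrial transcripts had lower medians in L597R. The epithelial markers had a median of -0.26 over 4 measured members (percentile 1.5, then 0.590), and with a pseudocount of 5 the list fell inside the middle 95% (-0.12, percentile 3.85). The tight junction gene OCLN was at 1.18 against 1.73 FPKM (read ratio 0.680, 0.566 to 0.817) and TJP1 at 2.60 against 3.23 (0.804, 0.708 to 0.913), while KRT18 was at 37.6 against 34.3. The mitochondrially encoded mRNAs had a median of -0.15 (percentile 1.54, then 0), with MT-ND5 at 587 against 737 FPKM. Of 13 members 3 lay above and 10 below P-Enter, with the interval above 1 for 1 and below 1 for 8. MT-ND2 was higher at 1033 against 950 FPKM. The GC trend was steepest in this comparison (Spearman -0.69 across genes), and the regression removed 47.4% of the variance between the libraries, against 18.1% for WT and P-Enter.

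**Figure D2:**
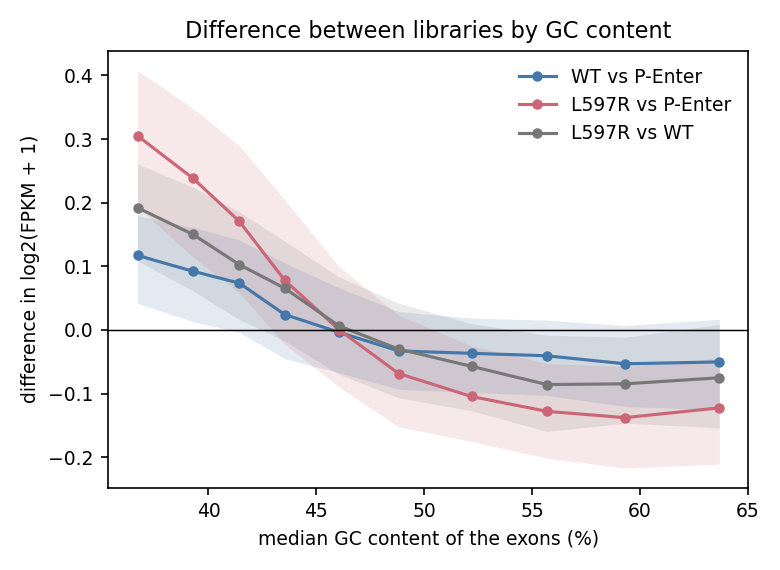
Median difference in log2(FPKM + 1) (y axis) of protein-coding genes in 10 equal groups by exon GC content (x axis, median GC percent of the group) for the 3 comparisons; points are medians and shaded bands run from the first to the last quartile. In L597R against P-Enter the median ran from 0.31 in the group lowest in GC to -0.12 in the highest, and in WT against P-Enter from 0.12 to -0.05.

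**Figure D3:**
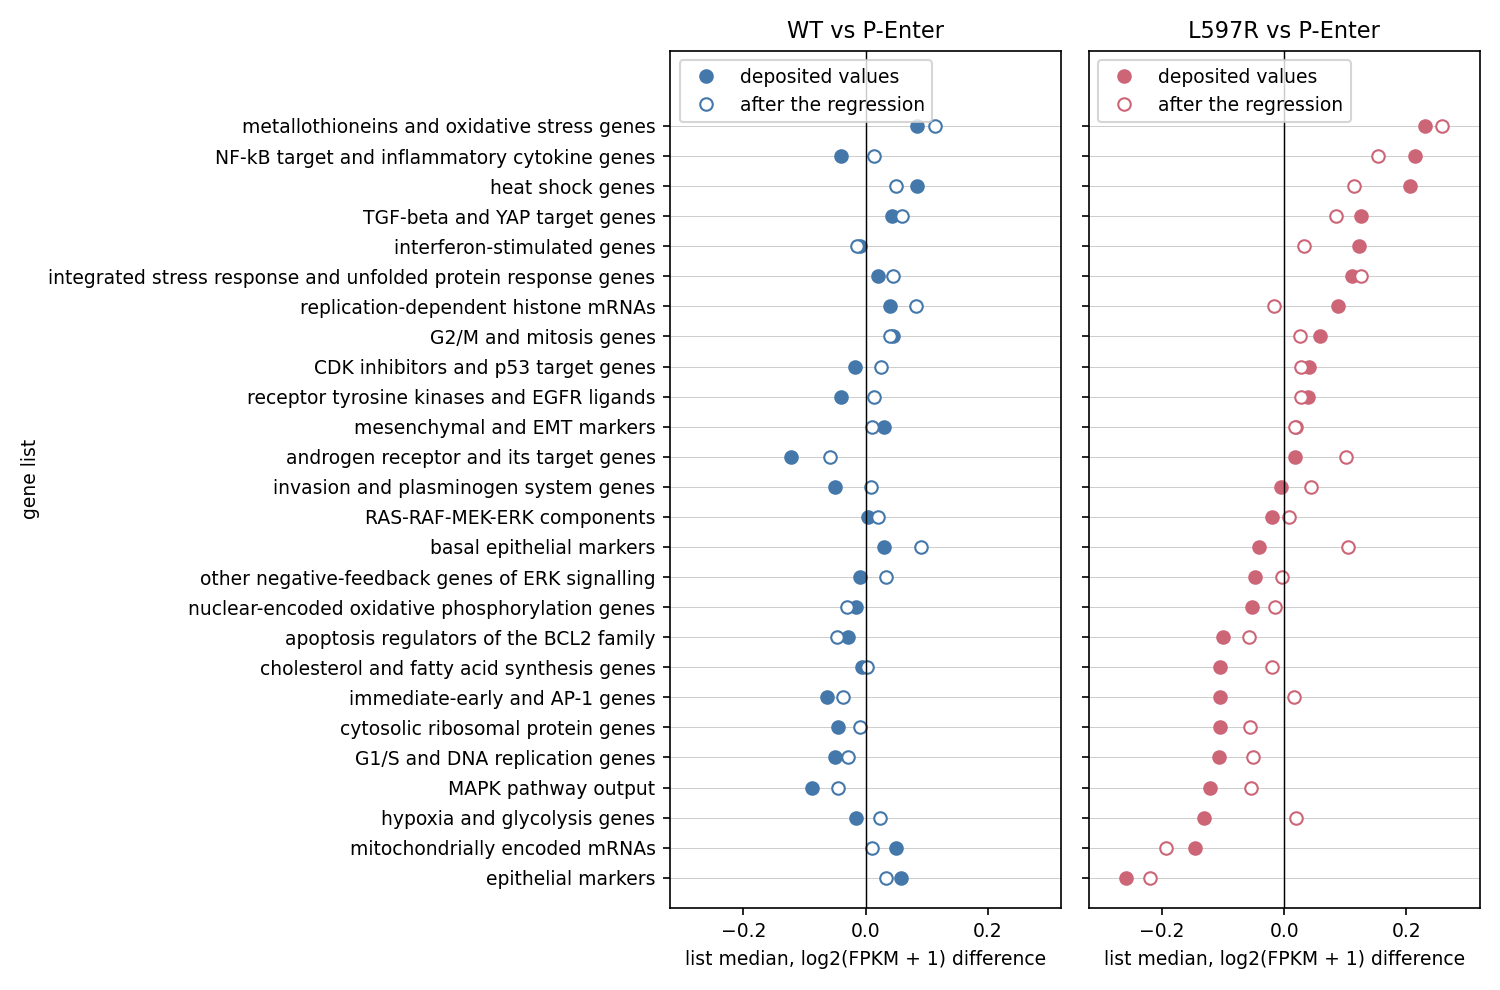
Median difference in log2(FPKM + 1) (x axis) of 26 gene lists (y axis) in WT against P-Enter (left) and L597R against P-Enter (right); filled points are the deposited values and open points follow the regression on gene length, GC content and expression. In L597R the metallothionein and oxidative stress genes lay at 0.23 and 0.26, and the epithelial markers at -0.26 and -0.22.

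The comparison of L597R with WT set the library with mutant BRAF against the one with wild-type BRAF. BRAF reads were also higher in L597R (read ratio 2.18, 2.05 to 2.31), so the mutation and the BRAF level cannot be told apart. MMP3 was higher in L597R than in WT as well, at 4.13 against 1.31 FPKM (read ratio 3.15, 2.18 to 4.66). CDK7 was at 8.23 FPKM in L597R against 1.96 in WT (4.21, 3.26 to 5.49), close to its 8.03 in P-Enter. RPS25 was lower at 1.39 against 8.73 (0.159, 0.107 to 0.229), and ELP5, a subunit of the Elongator complex, at 2.79 against 8.56 (0.326, 0.264 to 0.399). ELP5 was at 3.83 FPKM in P-Enter, so WT lay further from the control (log2 difference 0.98) than L597R did (-0.35). BRAF itself differed by 0.97 on the log2 scale, just short of the rule, and passed it with a pseudocount of 0.1 (1.11). ELP5 lies on chromosome 17 from 7251416 to 7259940.

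There were 77 genes past the rule, 37 higher and 40 lower in L597R, of which 58 were shorter than 200 bp, and the interval left out 1 for 27 of the 77. The balance of directions changed with the setting, to 97 higher and 92 lower with a pseudocount of 0.1 and to 29 and 22 with recovered reads and an interval beyond 1.5-fold. Protein-coding genes made up 7, of which CDK7, MMP3, MOAP1, H2BC17 and LY96 were higher and RPS25 and ELP5 lower, against 22 higher and 19 lower, BRAF left out, with recovered reads and that interval. MOAP1 was at 2.53 FPKM in P-Enter, 0.581 in WT and 2.62 in L597R. H2BC17 was at 1.45, 0.273 and 1.93 FPKM in that order, from 9, 2 and 15 reads. LY96, the co-receptor of TLR4, was at 2.91 against 0.914 FPKM from 27 and 8 reads. Of the genes of short RNAs, whose reads may belong to longer transcripts, MIR3685 had 12 reads in L597R and 4 in WT (ratio 2.83, 0.858 to 12.04). SNORD83A had 5 and 21 (0.225, 0.0662 to 0.612). MIR6739 had 2 and 10 (0.189, 0.0201 to 0.885), SNORD104 had 2 and 8 (0.236, 0.0244 to 1.18) and MIR4653 had 3 and 8 (0.354, 0.0605 to 1.47).

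The MAPK output median was -0.08 in L597R against WT (percentile 9.55, and 27.9 after the regression), with 2 of 8 members above WT. The immediate-early and AP-1 genes had a median of 0.00 (percentile 52.99), and of 0.07 after the regression (98.2). The NF-kB and cytokine genes had a median of 0.20 (99.7, then 99.9), with the interval above 1 for 5 of 11 and below 1 for 0. It fell inside the middle 95% at a mean of at least 5 FPKM (0.08, percentile 80.6) and with a pseudocount of 5 (0.07, 96.7). For the receptor tyrosine kinases and EGFR ligands (percentile 54.2) the interval lay above 1 for 3 of 11 and below 1 for 3. CXCL8 was at 2.80 against 1.28 FPKM (read ratio 2.18, 1.52 to 3.17). The metallothionein and oxidative stress genes had a median of 0.18 (percentile 100 both times), and the stress response and unfolded protein genes 0.09 (98.5, then 100). The epithelial markers had a median of -0.27 over 4 members (0.350, then 0.0300), but -0.02 at percentile 21.8 without a filter. The mitochondrially encoded mRNAs had a median of -0.14 (0.150, then 0). The replication-dependent histone mRNAs had a median of 0.15 (98.7, then 98.1), with the interval above 1 for 1 of 8 and below 1 for 1. They are poorly polyadenylated, and the libraries were made with an mRNA kit. The RAS-RAF-MEK-ERK components had a median of 0.08 (98.8, then 78.3). The GC trend in this comparison had a Spearman value of -0.59 across genes.

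WT and L597R shared 31 genes past the rule against P-Enter, 14 higher and 17 lower in both, and 3 genes lay in opposite directions. Independent lists of those sizes would share 0.445 genes. Unchanged libraries simulated against the same control shared 18.1 with counting error only and 30.97 with an assumed coefficient of variation of 0.2. They had 0.34 and 0.58 genes in opposite directions. Among genes of 200 bp or longer the overlap was 3, against 0.8 and 10.9 in those simulations and 0.0360 for independent lists. The covariance of the differences was 0.0367, against 0.0135 with counting error only and 0.0742 with the assumed variation. The single control library cannot be split, so part of any excess may come from it. The simulated libraries held no GC trend, while both comparisons followed GC content in the same direction (Spearman -0.45 for WT and -0.69 for L597R). Part of any excess may go with that trend too, which was not tested. NDUFS3 and SURF1 were lower in both, and BRAF was the protein-coding gene higher in both.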

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

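In this part the tests of counting error and of the length, GC and expression trend on the protein-coding genes were chosen after those genes had been seen, and so were the percentile at which the overlap test was taken to decide, the overlap in a wider set and the distances between genes.

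Of the genes past the rule in both comparisons with P-Enter, 3 lay in opposite directions, and the difference between WT and L597R was not tested. MIR6747 was at 1.22 in WT and -1.16 in L597R on the log2 scale, from 1 read in P-Enter, 4 in WT and 0 in L597R. SNORD18 was at 1.16 and -1.05 from the same numbers of reads, and RNU7-18P at -1.15 and 1.14 from 1, 0 and 4 reads.

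The first pattern was the 21 protein-coding genes other than BRAF past the 2-fold rule, such as CDK7 lower in WT, RPS25 lower in L597R and MMP3 higher in L597R. Counting error alone is argued against for the 13 with at least 100 reads over the libraries compared, since with intervals adjusted by Bonferroni for 28074 comparisons the read ratio left out 1 for 100% of them; for the 8 with fewer reads this held for 37.5%, so it stays open for the others. For the trend with length, GC content and expression, the corrected difference was 0.946 times the uncorrected one at the median. This ratio could hardly come out low, since the genes were chosen for a log2 difference of at least 1. Median differences of genes grouped by GC content ran only from -0.14 to 0.31 in L597R against P-Enter, where the trend was steepest. The ratio is thus no test of the trend. The medians show only that the GC trend by itself was smaller than the rule requires. For reads lost where exons of neighbouring genes overlap, 4 of the 21 had such an overlap, namely NDUFS3, RPS25, EEF1B2 and ELP5. That share was at percentile 40.2 of matched draws, inside their spread (median 19.0%, upper end of the middle 95% at 38.1%). Such a loss of reads thus stays open, although the bound set beforehand was the 50th percentile. With overlaps on the same strand alone the 21 genes were at percentile 67.7. A wider set of 104 genes past the read-based rule was at percentile 2.45 on either strand (20.2% against a median of 28.8%) and 6.45 on the same strand. Reads of single loci lost in alignment or counting could not be tested without the reads and stay open, as does an effect of the BRAF variants with 1 library each; of the 21, 4 (ATP5IF1 with MED18, SMDT1 with NDUFA6) had another within 100000 bp, against a median of 0 in draws matched on expression but not on gene density (percentile 100), and SMDT1 and NDUFA6 went apart.

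The next pattern was the higher list median of NF-kB target and cytokine genes in L597R than in P-Enter, at 0.21. No member passed the rule. Of 11 measured members 8 lay above P-Enter, CXCL8, CXCL2 and BIRC3 among them, and 3 below. The call depended on the filter: the list was at percentile 83.8 at a mean of at least 5 FPKM, where 5 of 11 members were left, and at 94.9 without a filter. With the filter of 1 FPKM neither the trend nor counting error accounts for all of it: after the regression the median was 0.15, at percentile 99.7 of matched lists, and the uncorrected median lay above 100% of 1000 simulated unchanged libraries, of which the middle 95% ended at 0.07. A difference between cultures or library preparations, or in the level of BRAF, cannot be separated from the mutant with 1 library each. An effect of the mutant on these transcripts was not tested.

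The last pattern was that 113 of the 169 genes past the rule in any comparison were shorter than 200 bp, SNORD93 and MIR6739 among them. Unchanged libraries simulated with counting error alone gave a median of 73 such genes, from 46 to 96 over 1000 simulations. Counting error is thus a candidate source of most of them, while the observed number lay above every simulation and the rest stays open. These 113 genes had a median of 7 reads over the 3 libraries.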

How the results depend on the processing

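No paired analysis was possible because each group had 1 library and no test was fitted; for the same reason no library could be left out. Recovered reads, the 200 bp limit and the regression were chosen after seeing the data. TMM, total-count and size-factor scaling and pseudocounts in reads were planned for counts and not run, since the files hold FPKM; rescaling by the median ratio was run instead. No result past its threshold changed sign in the settings run. Some list medians inside the middle 95% did: that of the immediate-early and AP-1 genes in L597R against P-Enter was -0.11, and 0.02 after the regression. Rescaling and leaving out mitochondrially encoded genes kept each count of genes within 1.5 times.

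The counts of genes past the rule (104 in WT against P-Enter, 86 in L597R against P-Enter, 77 in L597R against WT) depended on the low genes, and the cause was not tested beyond the settings. In that order they were 191, 203 and 189 with a pseudocount of 0.1, and 2, 7 and 3 with 5. With a pseudocount of 5, CDK7, TMEM14C, MMP3, EIF3K, EEF1B2 and ELP5 fell short of the rule in the comparisons for which they are named. RPS25 fell short in L597R against P-Enter (-0.81) and stayed past it in L597R against WT (-1.10). The counts were 267, 246 and 214 without a filter and 9, 13 and 8 at a mean of 5 FPKM. A threshold of 1.5 gave 233, 322 and 237, and 4 gave 16, 16 and 15. Protein-coding genes alone gave 11, 11 and 7, and 10, 9 and 7 after the regression. Genes of 200 bp or longer gave 28, 24 and 19. Recovered reads gave 52, 62 and 51 with an interval beyond 1.5-fold, 153, 202 and 146 beyond 1, and 98, 135 and 110 with an assumed coefficient of variation of 0.2. In both comparisons with P-Enter more genes were lower than higher in each of these settings, except 1 and 1 in WT with a pseudocount of 5; in L597R against WT the balance went either way.

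The overlap of 31 genes was 81 and 1 with pseudocounts of 0.1 and 5, 105 without a filter and 3 at a mean of 5 FPKM. It was 111 and 6 at thresholds of 1.5 and 4, 3 for protein-coding genes and 3 for genes of 200 bp or longer. With recovered reads it was 13 with the interval beyond 1.5-fold and 48 beyond 1. The cause was not tested.

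The BRAF difference of 1.03 in WT against P-Enter was 0.50 with a pseudocount of 5, short of the rule because the pseudocount exceeds both values. In L597R against WT it was 1.11 with a pseudocount of 0.1 and 1.12 with recovered reads, past the rule that 0.97 missed. The number of lists outside the middle 95% was 2 after the regression for WT against P-Enter. It was 4 at a mean of 5 FPKM and 5 without a filter for L597R against P-Enter, and 3 at a mean of 5 FPKM for L597R against WT; the cause was not tested. The NF-kB and cytokine list was among those lost at a mean of 5 FPKM in both (percentiles 83.8 and 80.6), where 5 of its 11 measured members were left. The genes past the rule had a median of 6 or 7 reads over the 2 libraries compared. For the protein-coding ones it was 171 in WT against P-Enter, 167 in L597R against P-Enter and 165 in L597R against WT. Whether depth limited the low genes was not tested.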

Other observations

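The list medians and their percentiles before the regression were planned. The other tests in this part were chosen after the values had been seen. Some genes short of the size rule differed in reads between the libraries. They were picked after their values were seen, and their intervals are not adjusted for the number of genes. MMP1, a collagenase next to MMP3 on chromosome 11, had 2 reads in P-Enter, 3 in WT and 24 in L597R (read ratio to P-Enter 9.61, 2.39 to 83.9). FOS, an immediate-early gene, had 5, 11 and 27 reads (4.32, 1.64 to 14.4). HKDC1, a hexokinase family member, had 22, 73 and 103 reads, with a ratio of 2.82 (1.73 to 4.76) for WT and 3.75 (2.35 to 6.24) for L597R against P-Enter. HRAS had 518, 303 and 456 reads, with a ratio of 0.496 (0.429 to 0.573) for WT.

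In L597R against P-Enter the EGFR ligands EREG and AREG were at 12.6 against 7.99 FPKM (read ratio 1.57, 1.43 to 1.74) and 6.79 against 4.90 (1.38, 1.09 to 1.77), while EGFR was at 36.2 against 34.1. These ratios are not corrected for the GC trend, which was steepest in this comparison. In WT against P-Enter the regression took the log2 difference of EREG from 0.14 to 0.02, while AREG stayed at -0.17. In L597R against P-Enter the list of receptor tyrosine kinases and EGFR ligands had a median of 0.04 (percentile 70.7, and 74.7 after the regression). ZEB1, a repressor of epithelial genes, was at 2.72 FPKM in P-Enter, 3.33 in WT and 4.79 in L597R (ratio to P-Enter 1.76, 1.54 to 2.02), and log2 differences corrected for the GC trend were 0.13 and 0.40. Its list of mesenchymal and EMT markers had a median of 0.02 in L597R against P-Enter (percentile 60.9, and 69.3 after the regression), with 5 members above and 4 below.

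Genes that passed the read-based rule tended to lie near each other. Of 104 protein-coding genes past it in any comparison, 27 had another within 100000 bp, against a median of 2 and an upper end of the middle 95% at 8 in draws matched on CPM but not on gene density. Of 16 neighbouring pairs past it in the same comparison, 15 had the same direction. Against P-Enter most genes past it were lower (10 higher and 36 lower in WT, 12 and 40 in L597R). Unrelated pairs there would thus often share a direction too. In L597R against WT 22 were higher and 19 lower. The pairs are not separate loci. PIP4K2B with MLLT6 counted in both comparisons with the single P-Enter library, and MED22, SURF6 and SURF4 on chromosome 9 were paired with each other. RPS25 and SLC37A4 on chromosome 11 were both lower in L597R than in P-Enter (log2 read ratios -2.15 and -1.80), as were EIF3K and ACTN4 on chromosome 19 (-1.53 and -1.25). SURF1 and SURF4 on chromosome 9 were both lower in WT (-1.80 and -1.32), while SMDT1 and NDUFA6 on chromosome 22 went apart in WT (1.57 and -2.35).

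Markers of cell identity were as follows. CDH1, the epithelial cadherin, had 1 read in P-Enter and 0 in WT and L597R, and KRT8 was at 0.623, 0.584 and 0.534 FPKM. KRT19 had 3, 0 and 1 reads, while KRT18 was at 34.3 FPKM in P-Enter. VIM was at 130 FPKM, AXL at 155 and CDH2 at 8.94 in P-Enter. The most abundant transcript was FTL, the ferritin light chain, at 6003 FPKM in P-Enter, 6329 in WT and 7065 in L597R. Genes that growing cells use were near 0 in the same files: ALDOA, a glycolytic enzyme, had 21, 15 and 13 reads, and NUSAP1, a mitotic spindle protein, had 3, 4 and 5. A value near 0 here thus does not tell absent transcripts from reads that were not counted, and the identity of the line was not tested. Immune, melanocyte and fibroblast, endothelial and erythroid marker lists had 0 members at a mean of 1 FPKM or more.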
